A study of Mus musculus with 22 samples.

How the data were processed

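RNA-seq was measured in 22 mouse cell libraries in 10 groups, taken from the sample titles and labels: C57_ESC, C57_PrESC, EPZ_iPrE1, EPZ_iPrE2, TG2A_ESC, KO10_SL_rescued, KO10_S2iL and TG2A_S2iL with 2 libraries each, and E14_ESC and KO10_SL with 3 each. Per the labels all but the C57 libraries come from E14 cells, and the labels give the culture as ESC medium with LIF, the same with 2i, or PrE stem cell medium. The labels describe the molecule as polyA RNA and the library kit as rRNA depletion, and these do not match, so the RNA selection is uncertain. The knockout and rescue genotypes are spelled "Eeh2" in the labels and were read as Ezh2, which the Ezh2 counts bear on directly. Human cells, the other knockout clone and the chromatin profiling mentioned for the series were not used here.

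The submitters' processing notes name Trim Galore, STAR 2.7.6a, DESeq2 and the genome build mm10. The authors deposited 1 table of expected counts per gene symbol, 55367 symbols in 22 columns, with no column for gene length and no scaling. The counting tool, the annotation and the strand setting are not given in the sources used here. The values are not all whole numbers: 5.71 to 7.26% of symbols held fractional values per library, with 27 to 37.2% of the counts, so the deposited values, which the plan had called raw counts, were treated as estimated counts and rounded to whole numbers before modelling. Reads that match several genes are therefore shared out by an unknown rule, and near-identical copies and overlapping genes on opposite strands are reported as uncertain.

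Library totals ran from 13.6 to 26.3 M estimated counts, 17495 to 21781 symbols were detected per library, and mitochondrial genes took 1.78 to 4.04% of counts. Pearson correlation of log2 CPM between replicates was 0.967 in C57_PrESC, 0.973 in C57_ESC and 0.988 to 0.997 in the other groups, over the 17547 tested genes. Symbols were matched to GENCODE M21 (GRCm38), whose version may differ from that of the authors: 53186 of the symbols and 17180 of the 17547 tested genes were found there exactly once. Locations were used only for the X, Y and mitochondrial genes and for overlaps.

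Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 10 groups, libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 22 libraries, leaving 12 residual degrees of freedom. Each comparison was a contrast in this fit, with Benjamini-Hochberg adjustment within the comparison, and a gene was called at an adjusted p below 0.05. CPM values use the TMM-scaled library sizes. A fold against a group with 0 counts is a lower bound from 3 counts over the group. The comparisons were EPZ_iPrE1 and EPZ_iPrE2 each against TG2A_ESC, C57_PrESC against C57_ESC, EPZ_iPrE2 against EPZ_iPrE1, the mean EPZ change less the C57 change, KO10_SL against E14_ESC and against TG2A_ESC, KO10_SL_rescued against KO10_SL and against E14_ESC, KO10_S2iL against TG2A_S2iL, each medium change, the knockout change under 2i less that in SL, and E14_ESC against TG2A_ESC. TG2A_ESC served as the SL control of the difference between media, because TG2A_S2iL is named after the same cells.

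The 22 gene lists were written before the data were examined: PrE transcription factors, PrE surface, uptake and basement membrane genes, parietal endoderm, visceral endoderm, naive pluripotency, general pluripotency, formative and primed, PRC2 subunits, PRC1 subunits, Hox, other PRC2 target developmental genes, primitive streak and mesoderm, neuroectoderm, trophoblast, 2-cell-like, germline, ERK response, Wnt response, DNA methylation enzymes, fibroblast (feeder), imprinted, and stress and p53 response. A macrophage list was added after the values were seen and used only as a summed level. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Over 13 comparisons this gave 70 list calls, and 22 when the correlation was estimated from the data, and the second p is printed beside each call it could change. Counts of list members use the adjustment over all genes; the count with adjustment over the list alone is given where it differs. The tests assume genes and libraries as sampled here, and replicate numbers were not taken as pairs.

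Genes named in the text followed a rule fixed before the data were examined: 12 landmark genes (Ezh2, Gata6, Gata4, Sox17, Sox7, Pdgfra, Nanog, Pou5f1, Sox2, Zfp42, Esrrb and Klf4), up to 4 called members of each list with the largest absolute change, and the 5 largest rises and falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries. Predicted gene models were counted but need not be named. Any name outside this rule is said to be chosen after its values were seen, or stands as a list member whose direction differs from that of its list. Overlap of called genes was tested by the Fisher exact test on genes tested in both comparisons.

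Alternatives planned before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of CPM at least 1 in at least 2 libraries, only the compared groups in the fit, the replicate number as a block, leaving out each library in turn, the other wild-type set, an absolute log2 change of at least 1, and an estimated correlation for the lists. Added after seeing the data were fits without the 4 libraries with the highest fibroblast sums, the overlap with TG2A_ESC as wild type and the PRC2 list without Ezh2. The pipeline was tested on simulated data with known changed genes, on lists of unchanged genes in those data, and on a simulated rescue with no effect. For KO10_SL against E14_ESC, edgeR called 51% of the simulated 2-fold changes and 79% of the 4-fold ones. For C57_PrESC against C57_ESC it called 41% and 70%, so a gene not called may still have changed. The simulation gave each gene the same spread in all groups. Replicates of C57_PrESC and C57_ESC correlated less (0.967 and 0.973) than those of the other groups (0.988 to 0.997). The simulated shares may therefore not hold for the C57 pair, and the simulation cannot show whether too many genes were called there. The values of 1 further gene were left out of the text and are not reported here.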

Results

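Gene expression was compared in mouse embryonic stem cells (ESCs) and in primitive endoderm (PrE) stem cells, the cultured form of the extraembryonic layer that lines the early blastocyst cavity. The 22 RNA-seq libraries fell into 10 groups. PrE stem cells came from a C57 line (C57_PrESC, n = 2) and from 2 E14-derived sets named EPZ iPrE1 and EPZ iPrE2 (n = 2 each). The labels place these sets in the PrE stem cell culture, and the plan describes both as lines derived with EPZ-6438. ESCs came from cells labelled C57 (n = 2) and from E14 cells in LIF medium, as 2 separate wild-type sets. Their titles are TG2A.NG.PB.ESC and ESC, and they are called TG2A_ESC (n = 2) and E14_ESC (n = 3) here. Ezh2 encodes the main methyltransferase of the Polycomb complex PRC2. Cells without it were held as clone 10 in the LIF medium, abbreviated SL in its name (KO10_SL, n = 3), and as the same clone after rescue (n = 2). The clone was also held in LIF medium with 2i inhibitors (KO10_S2iL, n = 2), beside the wild-type TG2A.NG.PB.S2iL, here TG2A_S2iL (n = 2). Library totals, in M of estimated counts, were 18.7 and 20 in C57_ESC, 15.7 and 17.8 in C57_PrESC, 13.6 and 13.9 in iPrE1, 16.1 and 16.2 in iPrE2, and 19.4 and 20.2 in TG2A_ESC. They were 16.2, 16.2 and 26.3 in E14_ESC, 24.3, 23.7 and 22.8 in KO10_SL, 17.8 and 18.6 in the rescued cells, 17.6 and 17.2 in KO10_S2iL, and 16.6 and 16.9 in TG2A_S2iL. The labels do not say whether replicates were separate cultures. Changes below are log2 fold changes, positive where the first-named group was higher, and levels are CPM, mean ± SD. The standard error (SE) is the absolute change divided by the square root of its quasi-likelihood F statistic. Where a group holds few counts, this SE is not a reliable measure of spread.

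Ezh2 was read first in every library. Its level was 239 and 194 CPM in C57_ESC, 118 and 131 in C57_PrESC, 137 and 138 in iPrE1, 135 and 141 in iPrE2, 194 and 199.8 in TG2A_ESC, 173, 181 and 184 in E14_ESC, and 222 and 214 in TG2A_S2iL. The knockout held 2, 1 and 1 Ezh2 counts in the SL libraries and 6 and 0 in the 2i libraries. The rescued libraries held 495 and 533 CPM, and Ezh2 was higher there than in E14_ESC by 1.52 (SE 0.14, adjusted p = 1.25e-04).

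**Figure D1:**
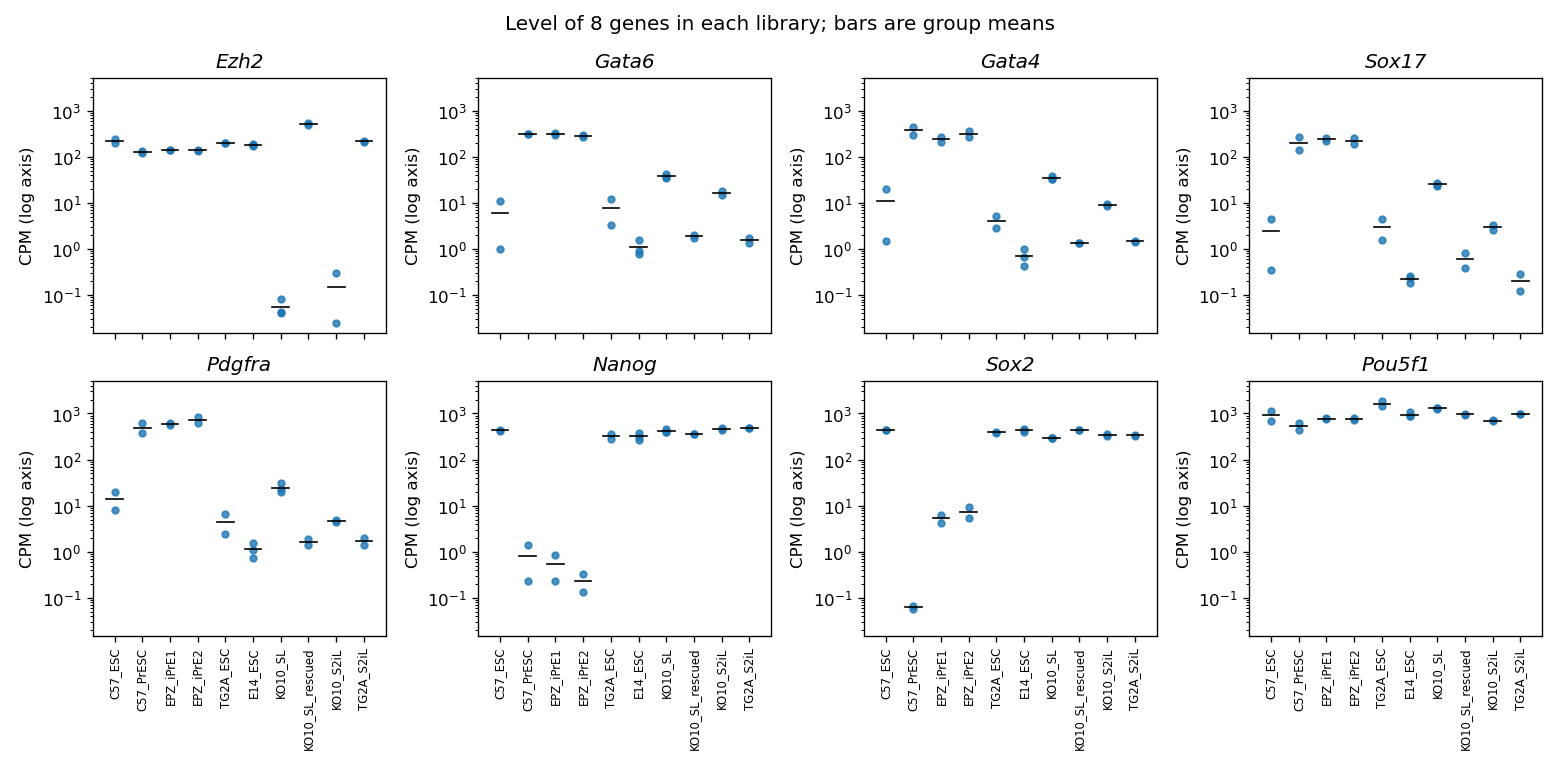
Level of 8 genes in each library (CPM, log axis), with bars at group means: Ezh2, the PrE genes Gata6, Gata4, Sox17 and Pdgfra, and the pluripotency genes Nanog, Sox2 and Pou5f1. A library with 0 counts is drawn near the bottom of its panel at a small positive value.

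The first question was how the E14-derived PrE stem cells differ from the ESCs of the same line. In iPrE1 against TG2A_ESC (n = 2 each), the GATA factors that specify PrE were among the higher genes: Gata6 stood at 311 ± 14 against 7.80 ± 6.39 CPM and rose by 5.32 (SE 0.623, adjusted p = 1.46e-06), and Gata4 rose by 5.89 (SE 0.669, adjusted p = 1.02e-06). The endoderm factors Sox17 (6.31, SE 0.578, adjusted p = 8.41e-08) and Sox7 (4.25, SE 0.445, adjusted p = 4.06e-07) rose as well, and Pdgfra, the receptor used to mark PrE cells, rose by 7.04 (SE 0.48, adjusted p = 2.79e-09) to 591 ± 52.2 against 4.47 ± 2.87 CPM. Nanog, a core naive pluripotency factor, fell by 9.19 (SE 0.402, adjusted p = 1.91e-11), and Sox2, the partner of Oct4, fell by 6.21 (SE 0.194, adjusted p = 6.04e-13). Pou5f1, which encodes Oct4, kept 771 ± 42.7 CPM against 1641 ± 304 CPM (-1.09 (SE 0.195, adjusted p = 1.35e-04)). Zfp42 (-3.87, SE 0.142, adjusted p = 3.12e-12) and Esrrb (-1.81, SE 0.401, adjusted p = 9.15e-04) fell, Klf4 was not called (0.88 (SE 0.486, adjusted p = 0.129)), and Ezh2 itself fell by 0.52 (SE 0.157, adjusted p = 0.00938). iPrE2 gave the same directions for these genes: Gata6 5.18 (SE 0.62), Gata4 6.29 (SE 0.678), Sox17 6.22 (SE 0.576), Sox7 4.55 (SE 0.449) and Pdgfra 7.34 (SE 0.485) rose. Nanog -10.37 (SE 0.436), Pou5f1 -1.11 (SE 0.195), Sox2 -5.72 (SE 0.187), Zfp42 -3.89 (SE 0.142) and Esrrb -1.88 (SE 0.401) fell there. Ezh2 fell too (-0.51 (SE 0.157, adjusted p = 0.00981)), and Klf4 was not called (0.54 (SE 0.484, adjusted p = 0.348)). The Ezh2 call ended without TG2A_ESC replicate 2 in iPrE1 (-0.47) and without iPrE2 replicate 1 in iPrE2 (-0.48). The Klf4 value passed the threshold with no filter on low counts in both sets, and with only the compared groups in iPrE1.

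Across all 17547 tested genes, edgeR called 10549 in iPrE1 (4892 up and 5657 down) and 10915 in iPrE2 (5060 up and 5855 down), of which 3236 and 3771, and 3341 and 4000, changed at least 2-fold. Of the PrE transcription factors in iPrE1, 8 rose, 0 fell and 2 were not called of 10 (adjusted p = 0.00394, adjusted p = 0.446 with an estimated correlation). Foxq1 rose by 7.30 (SE 0.657) and Foxa2, a pioneer factor of endoderm, by 6.51 (SE 0.752), while Hhex and Eomes were not called. Of the PrE surface, uptake and basement membrane genes, 15 rose, 1 fell and 1 were not called of 17 (adjusted p = 5.28e-10, adjusted p = 0.0336 with an estimated correlation). The collagen IV chains Col4a1 6.26 (SE 0.424) and Col4a2 6.57 (SE 0.419) and the proteoglycan core Srgn 7.18 (SE 0.817) rose, and Lrp2 fell (-1.02 (SE 0.37, adjusted p = 0.0246)). Of parietal endoderm genes 5 rose, 0 fell and 3 were not called of 8 (adjusted p = 0.00226, adjusted p = 0.0336 with an estimated correlation). The retinol receptor Stra6 7.51 (SE 0.445) and the hormone receptor Pth1r 5.48 (SE 0.362) were among the rises. Visceral endoderm genes moved both ways: 3 rose, 6 fell and 1 were not called of 10 (4 and 6 adjusted over the list alone, adjusted p = 0.637), with a list median of -2.78. The Wnt inhibitor Dkk1 7.57 (SE 0.603) rose and transferrin, Trf -6.51 (SE 0.88), fell. In iPrE2 PrE transcription factors gave 9 rose and 0 fell of 10, adjusted p = 0.00306, adjusted p = 0.408 with an estimated correlation. PrE surface genes gave 16 rose and 0 fell of 17, adjusted p = 3.54e-11, adjusted p = 0.0242 with an estimated correlation, with the endocytic receptor Cubn 6.63 (SE 1.30) among them. Parietal genes gave 5 rose and 0 fell of 8, adjusted p = 0.00227, adjusted p = 0.0242 with an estimated correlation, and visceral genes 4 rose and 6 fell of 10, adjusted p = 0.711.

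Called pluripotency genes mostly fell in both sets. In iPrE1, 0 rose, 8 fell and 6 were not called of 14 (adjusted p = 5.44e-07, adjusted p = 0.191 with an estimated correlation) in the naive list, such as Klf2 -8.62 (SE 0.316), Nr5a2 -6.97 (SE 0.312) and Prdm14 -6.58 (SE 0.435). In the general list 0 rose, 9 fell and 1 were not called of 10 (adjusted p = 9.03e-15, adjusted p = 0.00231 with an estimated correlation). Fgf4, the ligand that ESCs secrete to drive PrE fate, was at least 1541-fold lower, against a group at 0 counts, and Tdgf1 -11.66 (SE 0.494) fell. In the formative and primed list 1 rose, 9 fell and 0 were not called of 10 (adjusted p = 0.00509, adjusted p = 0.191 with an estimated correlation). Foxd3 -8.08 (SE 0.34) and Otx2 -5.54 (SE 0.745) were among the falls. In iPrE2 the naive list gave 0 rose and 8 fell of 14, adjusted p = 2.52e-07, adjusted p = 0.206 with an estimated correlation. The general list there gave 0 rose and 10 fell of 10, adjusted p = 8.5e-14, adjusted p = 0.00183 with an estimated correlation, and the formative list 1 rose and 9 fell of 10, adjusted p = 0.00783, adjusted p = 0.231 with an estimated correlation. Germline genes came to 1 rose and 10 fell of 14, adjusted p = 0.0223, adjusted p = 0.447 with an estimated correlation in iPrE1. In iPrE2 they came to 1 rose and 11 fell of 14, adjusted p = 0.0103, adjusted p = 0.408 with an estimated correlation. Examples in iPrE1 are Tex11 -4.38 (SE 0.476), Mael -3.91 (SE 0.422) and Hormad1 -4.30 (SE 0.524).

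Polycomb genes moved both ways. Of PRC2 subunits in iPrE1 3 rose, 8 fell and 2 were not called of 13 (adjusted p = 0.122). The accessory subunits Phf19 -4.66 (SE 0.681) and Jarid2 -1.56 (SE 0.12) and the core subunit Eed -1.66 (SE 0.161) fell, and Ezh1, the paralog of Ezh2, rose by 2.17 (SE 0.212). Of PRC1 subunits 7 rose, 7 fell and 2 were not called of 16 (7 and 8 adjusted over the list alone, adjusted p = 0.73). Phc1 -4.42 (SE 0.10) fell and Pcgf5 4.41 (SE 0.273) rose. That list had a median of -0.21 and a mean of 0.25. Hox genes, classical PRC2 targets, came to 15 rose and 0 fell of 33 with 14 and 0 over the list alone, adjusted p = 0.00773, adjusted p = 0.379 with an estimated correlation in iPrE1. In iPrE2 the Hox count was 12 rose and 1 fell of 33 with 11 and 1 over the list alone, adjusted p = 0.0967. In iPrE1 Hoxb4 6.0 (SE 0.404) rose, and Hoxb3 was at least 13.3-fold higher against a group at 0 counts. Other PRC2 target developmental genes came to 11 rose and 4 fell of 28, adjusted p = 0.499 in iPrE1 and 9 rose and 6 fell of 28, adjusted p = 0.795 in iPrE2.

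The remaining lists had no directed call in either set. ERK response genes in iPrE1 gave 5 rose and 5 fell of 14, adjusted p = 0.99, with Egr1 4.18 (SE 0.532) and Dusp4 3.48 (SE 0.421) up and Myc -3.99 (SE 0.228) down. Wnt response genes gave 6 rose and 3 fell of 10, adjusted p = 0.122, with the feedback inhibitors Nkd1 5.07 (SE 0.48) and Rnf43 4.81 (SE 0.433) up. Trophoblast genes gave 4 rose and 3 fell of 12, adjusted p = 0.731, with the simple-epithelium keratins Krt8 3.22 (SE 0.393) and Krt18 3.83 (SE 0.494) up. Primitive streak and mesoderm genes gave 1 rose and 3 fell of 10 with 1 and 1 over the list alone, adjusted p = 0.638, with Nodal -5.45 (SE 0.487) down. Neuroectoderm genes gave 1 rose and 4 fell of 8, adjusted p = 0.387, with Tubb3 -8.02 (SE 0.649) down. The 2-cell-like genes gave 0 rose and 4 fell of 9 with 0 and 3 over the list alone, adjusted p = 0.441, and DNA methylation enzymes 2 rose and 5 fell of 8, adjusted p = 0.499. Imprinted genes gave 6 rose and 5 fell of 18, adjusted p = 0.731, and stress and p53 genes 4 rose and 1 fell of 11, adjusted p = 0.499. The demethylases moved apart, Tet3 2.30 (SE 0.145) up and Tet1 -1.95 (SE 0.192) down. In iPrE2 ERK genes gave 5 rose and 6 fell of 14, adjusted p = 0.83, and Wnt genes 6 rose and 3 fell of 10, adjusted p = 0.13. Trophoblast genes there gave 3 rose and 6 fell of 12, adjusted p = 0.711, and streak genes 0 rose and 3 fell of 10, adjusted p = 0.587. Neuroectoderm genes gave 1 rose and 4 fell of 8, adjusted p = 0.29, and 2-cell-like genes 0 rose and 6 fell of 9 with 0 and 7 over the list alone, adjusted p = 0.331. DNA methylation enzymes gave 2 rose and 5 fell of 8, adjusted p = 0.711. Imprinted genes gave 9 rose and 7 fell of 18, adjusted p = 0.714, and stress genes 2 rose and 4 fell of 11, adjusted p = 0.937.

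Outside the lists, the largest rises with no overlap between libraries included Mageb2 in iPrE1 (at least 289-fold higher) and Mmp12 (at least 157-fold higher), Habp2 9.89 (SE 0.611) and the Fc receptor Fcgr3 9.66 (SE 0.933) in iPrE2. The matrix protease gene Mmp3 (24.7 ± 22.2 CPM in iPrE2, 13.3 ± 13.8 in iPrE1) and the fibroblast gene Postn (34.2 ± 29.4 CPM in iPrE2) were also among them and uneven between replicates. The largest falls included the ESC-expressed Ras gene Eras (at least 534-fold lower in iPrE1, at least 614-fold in iPrE2) and Khdc3 (at least 736-fold and at least 847-fold lower). Fibroblast genes, listed as a marker of feeder cells, came to 4 rose and 0 fell of 15 with 3 and 0 over the list alone, adjusted p = 0.499 in iPrE1 and 6 rose and 0 fell of 15, adjusted p = 0.42 in iPrE2. Their summed level was uneven between replicates: 197 and 31.8 CPM in iPrE1 and 65.4 and 327 in iPrE2, against 16.6 and 37.7 in TG2A_ESC. Relative library scaling by the RLE method moved the median of all genes to -0.123 in iPrE1 and -0.158 in iPrE2, from -0.075 and -0.109.

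The next question was whether the C57 PrE stem cells differ from C57 ESCs in the same genes. Both groups carry the C57 label, but whether they come from the same line is untested. The Y-linked gene Ddx3y, chosen after its values were seen, stood at 158 and 150 CPM in C57_PrESC and 0.053 and 2.98 in C57_ESC. A difference in line cannot be told apart here from the difference in cell type. In C57_PrESC against C57_ESC (n = 2 each), Gata6 stood at 306 ± 0.906 against 6.12 ± 7.23 CPM and rose by 5.65 (SE 0.637, adjusted p = 1e-06), and Gata4 (5.12, SE 0.625, adjusted p = 2.46e-06), Sox17 (6.37, SE 0.586, adjusted p = 9.39e-08), Sox7 (5.01, SE 0.447, adjusted p = 6.62e-08) and Pdgfra (5.16, SE 0.43, adjusted p = 2.98e-08) rose. The liver and endoderm factor Hnf4a rose by 6.95 (SE 0.731). Nanog fell by 9.09 (SE 0.38, adjusted p = 9.84e-12), Esrrb by 2.31 (SE 0.409, adjusted p = 1.22e-04) and Ezh2 by 0.80 (SE 0.157, adjusted p = 3.38e-04). Sox2 was close to absent, with 2 against 16841 counts. Pou5f1 fell by 0.76 (SE 0.194, adjusted p = 0.00289), a call that ended without C57_ESC replicate 1 (-0.33) and with only the compared groups. Zfp42 was not called (-0.24 (SE 0.129, adjusted p = 0.117)) but passed without C57_ESC replicate 2 (-0.47). Klf4 was not called (-0.28 (SE 0.482, adjusted p = 0.634)) and its sign turned with the library left out, at 1.38 without C57_ESC replicate 1 and -1.02 without replicate 2.

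In all, 10642 genes changed (4784 up and 5858 down, 2915 and 4098 of them by at least 2-fold), and 5383 with only the compared groups. Of PrE transcription factors 9 rose, 1 fell and 0 were not called of 10 (adjusted p = 0.00215, adjusted p = 0.217 with an estimated correlation), Eomes being the fall. Of PrE surface, uptake and basement membrane genes 15 rose, 1 fell and 1 were not called of 17 (adjusted p = 1.6e-10, adjusted p = 0.00626 with an estimated correlation). The cubilin partner Amn 6.37 (SE 0.444) and Col4a2 5.74 (SE 0.402) rose, and the activin antagonist follistatin, Fst -1.85 (SE 0.562), fell. For parietal genes 4 rose and 2 fell of 8, adjusted p = 0.00917, adjusted p = 0.0701 with an estimated correlation, with Stra6 6.95 (SE 0.418) and Pth1r 5.54 (SE 0.334) up. For visceral genes 3 rose and 5 fell of 10, adjusted p = 0.999, with the hedgehog ligand Ihh 8.11 (SE 0.628) and Dkk1 6.97 (SE 0.583) up and Trf -5.62 (SE 0.717) down. The naive list gave 2 rose and 8 fell of 14, adjusted p = 2.64e-05, adjusted p = 0.217 with an estimated correlation, where Dppa3 was at least 569-fold and Prdm14 at least 226-fold lower. Dppa3 was uneven in C57_ESC, at 13.6 and 91.2 CPM. Klf5 and Tbx3 were its rises (1.15 (SE 0.273) and 1.60 (SE 0.438)). The general list gave 0 rose and 8 fell of 10, adjusted p = 4.05e-15, adjusted p = 0.00373 with an estimated correlation, with Dppa4 -4.23 (SE 0.141) down. The formative list gave 0 rose and 9 fell of 10, adjusted p = 7.65e-04, adjusted p = 0.117 with an estimated correlation, with Zic2 -7.41 (SE 0.722) down. Germline genes gave 1 rose and 11 fell of 14 with 1 and 12 over the list alone, adjusted p = 2.64e-05, adjusted p = 0.145 with an estimated correlation, with Hormad1 at least 121-fold lower. Imprinted genes gave 3 rose and 13 fell of 18, adjusted p = 0.0156, adjusted p = 0.318 with an estimated correlation, with the falls Mest -8.03 (SE 0.618), Peg10 -4.79 (SE 0.353) and Snrpn -4.68 (SE 0.173).

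Among Polycomb genes in the C57 pair, PRC2 subunits gave 4 rose and 8 fell of 13, adjusted p = 0.0570, with Phf19 -8.36 (SE 0.788), Jarid2 -3.04 (SE 0.127) and Mtf2 -1.63 (SE 0.12) down and Phf1 1.43 (SE 0.211) up. PRC1 subunits gave 6 rose and 6 fell of 16, adjusted p = 0.547, with Phc1 -4.77 (SE 0.101) down and Pcgf5 3.75 (SE 0.26) and Bmi1 2.83 (SE 0.188) up. Hox genes gave 9 rose and 3 fell of 33 with 5 and 2 over the list alone, adjusted p = 0.222. Other PRC2 targets gave 7 rose and 11 fell of 28, adjusted p = 0.547, where the motor neuron factor Olig2 was at least 389-fold lower. The other lists had no directed call. Streak and mesoderm genes gave 1 rose and 6 fell of 10, adjusted p = 0.239. Neuroectoderm genes gave 0 rose and 5 fell of 8 with 0 and 6 over the list alone, adjusted p = 0.121, and trophoblast genes 2 rose and 8 fell of 12, adjusted p = 0.152. The 2-cell-like list gave 0 rose and 0 fell of 9, adjusted p = 0.574, and ERK genes 4 rose and 7 fell of 14, adjusted p = 0.864. Wnt genes gave 4 rose and 3 fell of 10 with 4 and 4 over the list alone, adjusted p = 0.731. DNA methylation enzymes gave 1 rose and 6 fell of 8, adjusted p = 0.0557, and stress genes 6 rose and 2 fell of 11, adjusted p = 0.221. Examples are Tfap2c -7.88 (SE 0.532), Dusp6 -3.30 (SE 0.554), Lef1 -5.05 (SE 0.734), Tet1 -2.74 (SE 0.198) and Atf3 5.67 (SE 0.342). The median of all genes moved from -0.091 to -0.122 under RLE scaling.

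Fibroblast genes gave 2 rose and 0 fell of 15 with 0 and 0 over the list alone, adjusted p = 0.642 in the C57 pair. Their sum was 32.0 and 2203 CPM in the 2 C57_PrESC libraries and 44.6 and 559 CPM in the 2 C57_ESC libraries, so 1 library of each group carried most of the signal. Collagen I (Col1a1) reached 709 CPM and periostin (Postn) 405 CPM in C57_PrESC replicate 2. Summed CPM of a macrophage list, chosen after the values were seen, was 37.5 and 145 in C57_PrESC and 4.07 to 17.3 in all other libraries. The Y-linked gene Usp9y, among the largest rises, was at least 238-fold higher in C57_PrESC, and the aquaporin Aqp8 9.21 (SE 0.71) also rose.

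**Figure D2:**
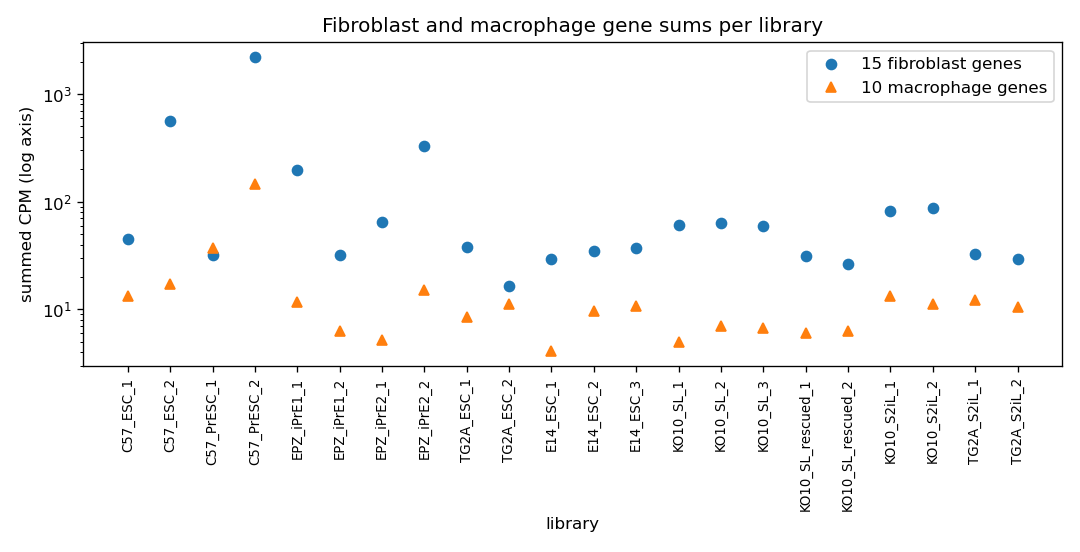
Summed CPM of 15 fibroblast and 10 macrophage genes in each library (log axis). The fibroblast sum was highest in C57_PrESC replicate 2, C57_ESC replicate 2, iPrE2 replicate 2 and iPrE1 replicate 1.

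The E14 and C57 changes were then compared with each other. Genes that rose in iPrE1 overlapped those that rose in C57_PrESC (3097 shared, Fisher exact odds ratio 11.2), and 3801 fell in both (9.79). For iPrE2 the numbers were 3150 (11) and 3945 (10.6). Fold changes correlated across genes, which are not independent, at r = 0.678 for iPrE1 and 0.693 for iPrE2. A direct test of the difference between the mean iPrE change and the C57 change called 6167 genes (3307 positive and 2860 negative). Among the landmark genes, the difference was positive for Pdgfra (2.03 (SE 0.534, adjusted p = 0.00703)) and Sox2 (6.65 (SE 0.44, adjusted p = 2.14e-08)) and negative for Zfp42 (-3.64 (SE 0.171, adjusted p = 6.35e-10)). The other 9 were not called, among them Ezh2 (0.29 (SE 0.207, adjusted p = 0.316)), Gata6 (-0.40 (SE 0.747, adjusted p = 0.751)) and Nanog (-0.69 (SE 0.643, adjusted p = 0.452)). For imprinted genes the difference was positive in 11, negative in 0 and not called in 7 of 18 (adjusted p = 3.34e-05, adjusted p = 0.398 with an estimated correlation), with H19 7.68 (SE 1.45) and Peg3 3.87 (SE 0.248) as examples. For germline genes it was positive in 5 and negative in 1 of 14 (adjusted p = 0.0195, adjusted p = 0.565 with an estimated correlation), with Sycp1 8.23 (SE 0.642) the largest. With only the compared groups the count of genes was 3041. The 2 sides differ in cell line, and whether C57_PrESC and C57_ESC share a line is untested.

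The 2 E14 sets were compared directly, iPrE2 against iPrE1 (n = 2 each). No landmark gene was called, for example Gata6 (-0.14 (SE 0.502, adjusted p = 0.988)) and Sox2 (0.49 (SE 0.194, adjusted p = 0.212)), and 686 genes were (307 up and 379 down). Genes named here were chosen after their values were seen. The maternally expressed imprinted RNAs Meg3 (6.05 (SE 1.01, adjusted p = 0.00195)), Rian (6.76 (SE 0.947, adjusted p = 4.74e-04)) and Mirg (6.15 (SE 1.15, adjusted p = 0.00453)), which share a locus, were higher in iPrE2. The paternally expressed Mest (-4.89 (SE 0.578, adjusted p = 1.02e-04)) and the trophoblast and germ cell factor Tfap2c (-4.61 (SE 0.526, adjusted p = 8.39e-05)) were lower. Hox genes gave 0 rose and 1 fell of 33, adjusted p = 0.00905, adjusted p = 0.556 with an estimated correlation. Trophoblast genes gave 0 rose and 1 fell of 12 with 1 and 3 over the list alone, adjusted p = 0.00143, adjusted p = 0.243 with an estimated correlation. Stress and p53 genes gave 0 rose and 0 fell of 11, adjusted p = 0.0131, adjusted p = 0.243 with an estimated correlation. These 3 calls were toward lower values in iPrE2. The number of called genes was 393 without iPrE1 replicate 1, 379 without iPrE1 replicate 2, 407 without iPrE2 replicate 1 and 397 without iPrE2 replicate 2. It was 28 with only the compared groups and 1143 with no filter on low counts.

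The effect of losing Ezh2 was read in KO10_SL against E14_ESC (n = 3 each), although the labels do not say which wild-type set is the matched control of clone 10. All knockout and rescued libraries come from this 1 clone. Their p-values therefore measure spread between libraries, not between knockout clones. PrE regulators rose from low levels: Gata6 stood at 37.6 ± 4.27 against 1.08 ± 0.42 CPM and rose by 5.15 (SE 0.595, adjusted p = 3.26e-06). Gata4 rose by 5.63 (SE 0.645, adjusted p = 2.93e-06), Sox17 by 6.71 (SE 0.639, adjusted p = 4.59e-07), Sox7 by 4.18 (SE 0.438, adjusted p = 1.2e-06) and Pdgfra by 4.50 (SE 0.422, adjusted p = 4.06e-07). Mean Gata6 was 37.6 CPM in the knockout and 311 CPM in iPrE1. The pluripotency factors Nanog (0.37 (SE 0.192, adjusted p = 0.118)), Zfp42 (0.16 (SE 0.103, adjusted p = 0.225)), Esrrb (-0.21 (SE 0.316, adjusted p = 0.609)) and Klf4 (0.44 (SE 0.394, adjusted p = 0.378)) were not called, and Sox2 fell by 0.56 (SE 0.119, adjusted p = 0.00101). Nanog passed the threshold by DESeq2, with no filter on low counts and with only the compared groups. Klf4 passed in the latter 2, and Esrrb in the last. Pou5f1 rose by 0.47 (SE 0.158, adjusted p = 0.0214), a call that ended without E14_ESC replicate 1 (0.43), E14_ESC replicate 2 (0.42), KO10_SL replicate 2 (0.43) or KO10_SL replicate 3 (0.43).

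In all 8524 genes changed, 4534 up and 3990 down, 2173 and 1389 of them by at least 2-fold. With the CPM filter 4124 rose and 4167 fell. Of PrE transcription factors 8 rose, 1 fell and 1 were not called of 10 (adjusted p = 2.14e-04, adjusted p = 0.269 with an estimated correlation). Foxq1 6.09 (SE 0.638) rose and Hnf4a fell (-1.29 (SE 0.448)). Of PrE surface, uptake and basement membrane genes 14 rose, 0 fell and 3 were not called of 17 (adjusted p = 1.4e-13, adjusted p = 0.0154 with an estimated correlation). Srgn 5.62 (SE 0.714), Col4a2 4.67 (SE 0.318), and the endocytic adaptor Dab2 4.64 (SE 0.478) rose. Parietal genes gave 5 rose and 0 fell of 8, adjusted p = 0.00337, adjusted p = 0.0369 with an estimated correlation, among them Pth1r 4.18 (SE 0.31) and thrombomodulin, Thbd 3.78 (SE 0.924). Visceral genes gave 5 rose and 0 fell of 10, adjusted p = 0.188, with Dkk1 6.88 (SE 0.714) the largest rise. Of Hox genes 32 rose, 0 fell and 1 were not called of 33 (adjusted p = 3.01e-15, adjusted p = 0.0154 with an estimated correlation). Hoxd11 was at least 60.5-fold and Hoxb2 at least 22.9-fold higher against groups at 0 counts, and Hoxa10 went to 1530 against 4 counts. Hoxa11 (1040 against 2 counts) and its antisense RNA Hoxa11os (925 against 1 counts) overlap, so their counts are uncertain. Other PRC2 target genes gave 20 rose and 0 fell of 28, adjusted p = 3.02e-06, adjusted p = 0.0369 with an estimated correlation, with Pax9 at least 34-fold and Foxc1 at least 9.94-fold higher and the limb factor Tbx15 at 488 against 3 counts.

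Other lineage lists were tested in the same way. Of 2-cell-like genes 9 rose, 0 fell and 0 were not called of 9 (adjusted p = 3.02e-06, adjusted p = 0.13 with an estimated correlation), with Tcstv3 6.10 (SE 0.643) and the retrogene Zfp352 4.64 (SE 0.741) up. The Zscan4 copies share nearly identical sequence, so the value of Zscan4c (4.28 (SE 0.723)) is uncertain. Trophoblast genes gave 7 rose and 1 fell of 12, adjusted p = 0.00506, adjusted p = 0.13 with an estimated correlation, with Esx1 3.34 (SE 0.225), Tfap2a 3.18 (SE 0.414) and Gata3 2.87 (SE 0.617) up. Streak and mesoderm genes gave 4 rose and 0 fell of 10, adjusted p = 0.244, with Hand1 3.48 (SE 0.556) up. Neuroectoderm genes gave 4 rose and 0 fell of 8, adjusted p = 0.293, with Zic1 5.36 (SE 1.10) up. Germline genes gave 7 rose and 2 fell of 14, adjusted p = 0.0729, with Mael 2.89 (SE 0.282) and Dazl 1.69 (SE 0.25) up. Of PRC2 subunits 1 rose, 7 fell and 5 were not called of 13 (adjusted p = 9.48e-05, adjusted p = 0.0154 with an estimated correlation). The elongin-binding subunit Epop 1.95 (SE 0.157) rose and Ezh1 -1.45 (SE 0.173) fell. This list holds Ezh2, lower by design. The other 12, a set chosen after the values were seen, gave 1 rose and 6 fell with no directed call (adjusted p = 0.355). PRC1 subunits gave 7 rose and 4 fell of 16, adjusted p = 0.505, where Cbx8 3.54 (SE 0.296) rose and Cbx7 -1.20 (SE 0.109) fell.

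DNA methylation enzymes gave 1 rose and 5 fell of 8, adjusted p = 0.0430, adjusted p = 0.123 with an estimated correlation, with Tet1 -1.78 (SE 0.155) and Dnmt1 -0.76 (SE 0.0920) down and Dnmt3l 1.48 (SE 0.226) up. Stress and p53 genes gave 1 rose and 6 fell of 11 with 2 and 6 over the list alone, adjusted p = 0.0170, adjusted p = 0.13 with an estimated correlation, with Bbc3 -1.80 (SE 0.153) and Mdm2 -1.07 (SE 0.137) down. No directed call was made for the other lists. Naive genes gave 4 rose and 0 fell of 14, adjusted p = 0.505, with Dppa5a 1.16 (SE 0.231) up. General genes gave 1 rose and 2 fell of 10, adjusted p = 0.74, and formative genes 2 rose and 2 fell of 10, adjusted p = 0.739. ERK genes gave 2 rose and 4 fell of 14, adjusted p = 0.669, with Egr1 -2.47 (SE 0.434) down. Wnt genes gave 4 rose and 1 fell of 10, adjusted p = 0.74, and fibroblast genes 1 rose and 0 fell of 15, adjusted p = 0.681. Imprinted genes gave 4 rose and 6 fell of 18, adjusted p = 0.669, with Mest -4.62 (SE 0.487) down. The long noncoding RNA Lncenc1 also fell (31.1 ± 0.897 against 334 ± 10.9 CPM).

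**Figure D3:**
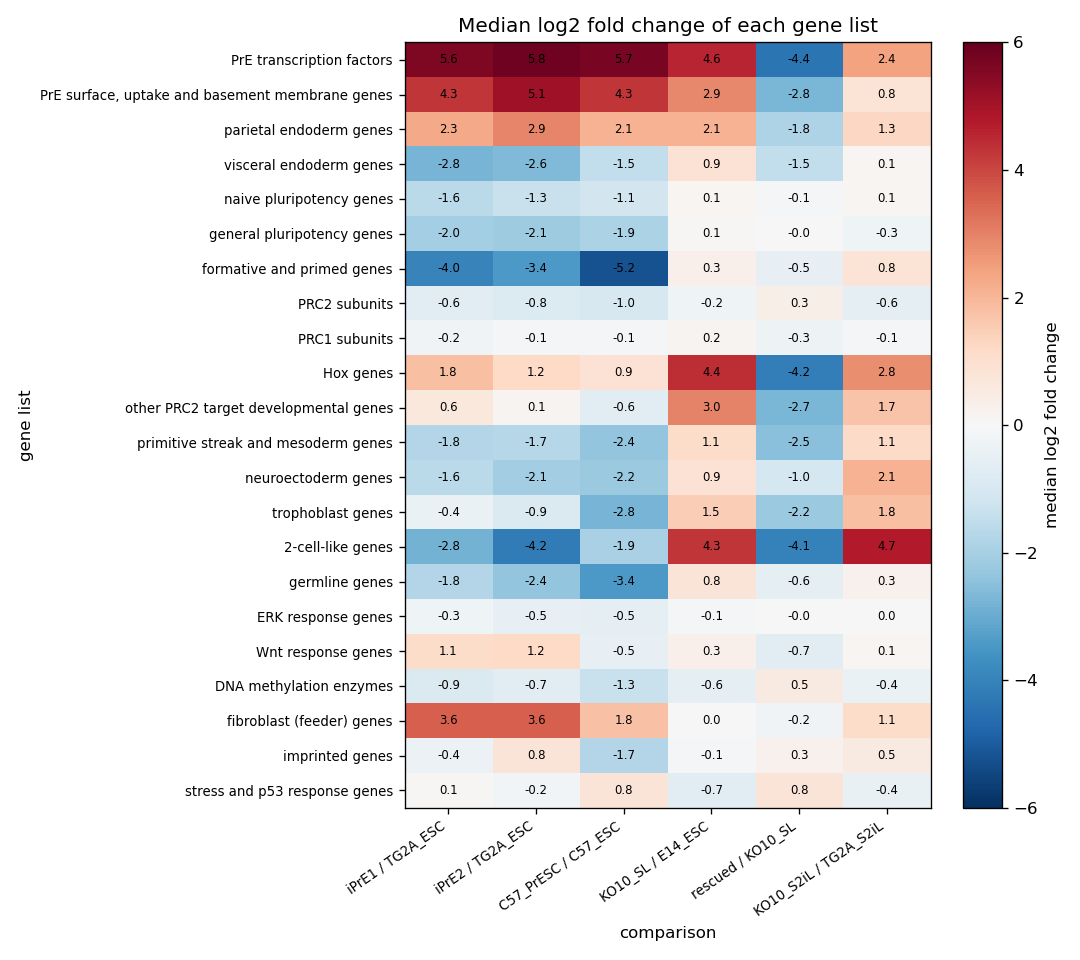
Median log2 change of each gene list in 6 comparisons, with genes at 0 counts in 1 group held at their 3-count bound. Medians show direction only, and the counts and tests are in the text.

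The choice of wild-type libraries mattered for the number of genes and for the size of the PrE rise. The median change of PrE transcription factors was 2.669 against TG2A_ESC and 4.556 against E14_ESC, and that of PrE surface genes 2.465 and 2.902. Against TG2A_ESC, 4863 genes changed in KO10_SL, 3751 of them also called against E14_ESC: 1826 up in both, 1809 down in both and 116 in opposite directions. Against TG2A_ESC the counts of members up and down were 8 and 0 for PrE transcription factors, 13 and 0 for PrE surface genes, 27 and 0 for Hox genes, 15 and 1 for other PRC2 targets and 9 and 0 for 2-cell-like genes. Naive genes gave 1 and 2 instead of 4 and 0, and general genes 0 and 4 instead of 1 and 2. The signs of Pou5f1 (-0.33 (SE 0.175, adjusted p = 0.172)) and Hnf4a (1.39 (SE 0.606, adjusted p = 0.098)) turned there, and neither was called. Gata6 rose by 2.27 (SE 0.542, adjusted p = 0.00507) there. The 2 wild types differed by 4270 genes (1972 up and 2298 down in E14_ESC). Gata6 (-2.88 (SE 0.674, adjusted p = 0.00531)), Sox17 (-3.64 (SE 0.84, adjusted p = 0.00482)), Sox7 (-2.30 (SE 0.52, adjusted p = 0.00425)) and Pdgfra (-2.04 (SE 0.51, adjusted p = 0.00806)) were lower in E14_ESC. Nanog (0.0 (SE 0.214, adjusted p = 1.0)), Sox2 (0.15 (SE 0.134, adjusted p = 0.473)) and Ezh2 (-0.13 (SE 0.142, adjusted p = 0.551)) were not called. That count was 1676 without TG2A_ESC replicate 2.

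The rescued cells tested whether these changes follow Ezh2. Against KO10_SL (n = 2 and 3), Ezh2 rose by 13.02 (SE 0.265), and Gata6 fell by 4.32 (SE 0.655, adjusted p = 6.06e-05) to 1.88 ± 0.238 CPM. Gata4 fell by 4.71 (SE 0.702, adjusted p = 5.24e-05), Sox17 by 5.37 (SE 0.664, adjusted p = 8.55e-06), Sox7 by 4.23 (SE 0.527, adjusted p = 9.19e-06) and Pdgfra by 3.88 (SE 0.47, adjusted p = 7.06e-06). Sox2 rose by 0.58 (SE 0.132, adjusted p = 0.00198). Nanog (-0.21 (SE 0.215, adjusted p = 0.449)), Zfp42 (-0.02 (SE 0.115, adjusted p = 0.904)), Esrrb (0.17 (SE 0.352, adjusted p = 0.725)), Klf4 (-0.14 (SE 0.441, adjusted p = 0.824)) and Pou5f1 (-0.45 (SE 0.178, adjusted p = 0.0514)) were not called, though Pou5f1 passed by DESeq2, under RLE scaling, with no filter on low counts and with only the compared groups, and Nanog and Esrrb in the last. Of the 7896 genes that changed, 3671 rose and 4225 fell, 1339 and 2174 of them by at least 2-fold. The balance turned without rescued replicate 1 (2857 rose and 2537 fell) and without KO10_SL replicate 1 (3618 and 3555), and was level with the CPM filter (3851 and 3849).

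On rescue, PrE transcription factors gave 0 rose and 8 fell of 10, adjusted p = 3.25e-04, adjusted p = 0.244 with an estimated correlation. PrE surface genes gave 0 rose and 14 fell of 17, adjusted p = 2.87e-11, adjusted p = 0.0192 with an estimated correlation. Parietal genes gave 0 rose and 5 fell of 8, adjusted p = 0.00361, adjusted p = 0.0334 with an estimated correlation, and visceral genes 0 rose and 5 fell of 10, adjusted p = 0.124. Examples are Foxq1 -5.76 (SE 0.74), Srgn -5.32 (SE 0.832), Col4a2 -4.54 (SE 0.377), Pth1r -4.89 (SE 0.40) and Dkk1 -5.63 (SE 0.744). Hox genes gave 0 rose and 29 fell of 33 with 0 and 30 over the list alone, adjusted p = 6.24e-13, adjusted p = 0.0192 with an estimated correlation, with Hoxd11 at least 36.9-fold and Hoxc9 at least 36.2-fold lower. Other PRC2 targets gave 0 rose and 21 fell of 28, adjusted p = 5.33e-06, adjusted p = 0.0342 with an estimated correlation, with Pax9 at least 20.7-fold lower. Trophoblast genes gave 1 rose and 8 fell of 12, adjusted p = 0.00160, adjusted p = 0.10 with an estimated correlation, with Krt8 -3.96 (SE 0.417) and Gata3 -3.71 (SE 0.786) down. The 2-cell-like genes gave 0 rose and 9 fell of 9, adjusted p = 9.09e-05, adjusted p = 0.217 with an estimated correlation, with Zfp352 -5.45 (SE 0.956) down. PRC2 subunits gave 5 rose and 1 fell of 13, adjusted p = 1.03e-05, adjusted p = 0.0192 with an estimated correlation, but that list holds Ezh2. The 12 without it gave 4 rose and 1 fell with no directed call (adjusted p = 0.363), with Lcor 1.01 (SE 0.155) and Mtf2 0.70 (SE 0.105) up and Epop -1.89 (SE 0.182) down. DNA methylation enzymes gave 6 rose and 2 fell of 8, adjusted p = 0.0274, adjusted p = 0.0842 with an estimated correlation, with Tet1 1.87 (SE 0.167) up and Dnmt3l -1.59 (SE 0.262) down. The other lists had no directed call. Naive genes gave 1 rose and 3 fell of 14, adjusted p = 0.548, and general genes 2 rose and 0 fell of 10, adjusted p = 0.811. Formative genes gave 1 rose and 4 fell of 10, adjusted p = 0.582. PRC1 subunits gave 5 rose and 6 fell of 16 with 6 and 7 over the list alone, adjusted p = 0.548, with Cbx8 -4.27 (SE 0.376) down. Streak genes gave 0 rose and 5 fell of 10 with 0 and 6 over the list alone, adjusted p = 0.0608, and neuroectoderm genes 0 rose and 4 fell of 8, adjusted p = 0.363. Germline genes gave 2 rose and 5 fell of 14, adjusted p = 0.548, with Mael -2.14 (SE 0.317) down. ERK genes gave 4 rose and 2 fell of 14, adjusted p = 0.588, with Egr1 3.33 (SE 0.463) up. Wnt genes gave 1 rose and 4 fell of 10 with 1 and 5 over the list alone, adjusted p = 0.588, and fibroblast genes 0 rose and 1 fell of 15, adjusted p = 0.548. Imprinted genes gave 6 rose and 2 fell of 18, adjusted p = 0.363, with Mest 4.27 (SE 0.517) up. Stress genes gave 6 rose and 1 fell of 11 with 7 and 1 over the list alone, adjusted p = 0.0709.

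**Figure D4:**
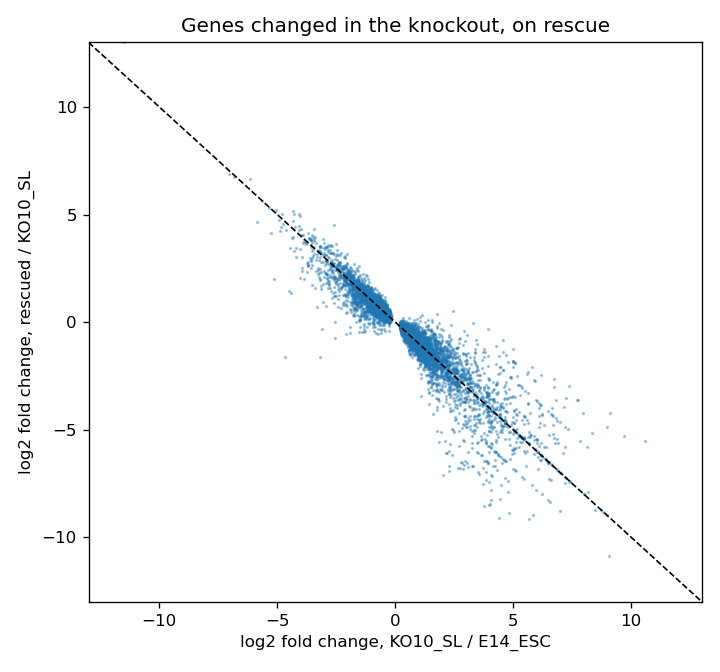
Log2 change in KO10_SL against E14_ESC and in rescued cells against KO10_SL for each gene called in the knockout, with full reversal as a dashed line. Ezh2 lies on the upper edge.

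Of the 8524 genes called in the knockout, 6820 were called in the opposite direction on rescue and 1 in the same direction. The median gene recovered 0.995 of its change (SD 0.00784 over the rescued replicates). KO10_SL stands in both changes, so its own noise raises this count. In data simulated with no rescue, 1 of 8899 called genes came back. With no true difference there, the adjustment passes almost no gene. The simulation therefore does not size the part of shared noise in the measured count. The selection was then made on the 5263 genes called in the 2i comparison, whose libraries are separate, though its knockout is the same clone. Of these, 2582 (49.1%) were called in the opposite direction on rescue and 482 in the same direction. That 2582 was 1688 without rescued replicate 2, 1617 without KO10_S2iL replicate 1, 1625 without TG2A_S2iL replicate 1 and 1533 without TG2A_S2iL replicate 2. As shares of the genes selected in each of these fits, these are 36.4, 53, 55.7 and 53.8%. Against E14_ESC directly (n = 2 and 3), the rescued cells differed in 19 genes by edgeR (5 up and 14 down) and in 177 by DESeq2, with 1588 at an unadjusted p under 0.05. The named ones were chosen after their values were seen: Ezh2 1.52 (SE 0.14) and the placental homeobox gene Esx1 1.70 (SE 0.238) were higher, and Krt8 -2.18 (SE 0.40) and Ptpn14 -1.21 (SE 0.131) lower. Gata6 was not called (0.83 (SE 0.832, adjusted p = 0.838)). PRC2 subunits with Ezh2 among them gave 1 rose and 0 fell of 13 with 1 and 1 over the list alone, adjusted p = 0.0149, adjusted p = 0.162 with an estimated correlation. The 12 without Ezh2 gave 0 rose and 0 fell with 0 and 1 over the list alone, and had no directed call (adjusted p = 0.976). Streak and mesoderm genes had a call toward lower values (0 rose and 0 fell of 10, adjusted p = 0.0299, adjusted p = 0.162 with an estimated correlation). Germline genes had a call toward higher values (0 rose and 0 fell of 14, adjusted p = 0.00181, adjusted p = 0.439 with an estimated correlation). The 19 fell to 9 without E14_ESC replicate 2, 5 without E14_ESC replicate 3, 4 without rescued replicate 1 and 1 without rescued replicate 2, and rose to 551 with only the compared groups and 389 with no filter on low counts. With the replicate number as a block it was 6, and against TG2A_ESC the rescued cells differed in 3798 genes.

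Loss of Ezh2 was also read under 2i in the same clone, in KO10_S2iL against TG2A_S2iL (n = 2 each). Gata6 stood at 16.4 ± 2.66 against 1.54 ± 0.281 CPM and rose by 3.40 (SE 0.714, adjusted p = 0.00219). Gata4 rose by 2.62 (SE 0.758, adjusted p = 0.0160) and Sox17 by 3.82 (SE 1.03, adjusted p = 0.0105), calls that ended with some libraries left out. For Gata4 these were KO10_S2iL replicate 2 (2.52), TG2A_S2iL replicate 1 (2.59) and TG2A_S2iL replicate 2 (2.61). For Sox17 they were KO10_S2iL replicate 1 (3.61), TG2A_S2iL replicate 1 (3.31) and TG2A_S2iL replicate 2 (4.56). Sox7 (2.22 (SE 0.98, adjusted p = 0.0991)) and Pdgfra (1.46 (SE 0.545, adjusted p = 0.0525)) were not called, although both passed by DESeq2, with no filter on low counts and with only the compared groups, and Pdgfra also under RLE scaling and with the block. Nanog (-0.05 (SE 0.234, adjusted p = 0.902)), Sox2 (0.02 (SE 0.146, adjusted p = 0.944)), Esrrb (0.04 (SE 0.387, adjusted p = 0.956)), Klf4 (0.49 (SE 0.482, adjusted p = 0.485)) and Pou5f1 (-0.49 (SE 0.193, adjusted p = 0.0679)) were not called, and Zfp42 fell by 0.52 (SE 0.126, adjusted p = 0.00575). Klf4 and Pou5f1 passed with no filter on low counts and with only the compared groups. In all 5263 genes changed, 2754 up and 2509 down, 2018 and 375 of them by at least 2-fold. Under RLE scaling 2969 rose and 2077 fell, with the median of all genes at 0.062 instead of 0.011, and with no filter on low counts 3334 rose and 1817 fell. The balance turned with the CPM filter (2608 rose and 2671 fell), without TG2A_S2iL replicate 1 (1311 and 1605) and without TG2A_S2iL replicate 2 (1354 and 1493). The total was 3053 without KO10_S2iL replicate 1, 3156 without KO10_S2iL replicate 2, 2916 without TG2A_S2iL replicate 1, 2847 without TG2A_S2iL replicate 2, and 9607 with only the compared groups.

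Under 2i, PrE transcription factors gave 4 rose and 0 fell of 10 with 5 and 0 over the list alone, adjusted p = 0.0450, adjusted p = 0.515 with an estimated correlation. That call was lost (adjusted p = 0.0514) when Ezh2 was left out of the PRC2 list, through the adjustment over lists. PrE surface genes gave 8 rose and 0 fell of 17 with 9 and 0 over the list alone, adjusted p = 9.63e-05, adjusted p = 0.132 with an estimated correlation, with Col4a2 4.06 (SE 0.395), Col4a1 3.41 (SE 0.384) and Amn 2.64 (SE 0.596) up. Parietal genes gave 4 rose and 0 fell of 8 with 5 and 0 over the list alone, adjusted p = 0.0604 and visceral genes 1 rose and 0 fell of 10 with 0 and 0 over the list alone, adjusted p = 0.865. Hox genes gave 18 rose and 0 fell of 33 with 21 and 0 over the list alone, adjusted p = 1.75e-09, adjusted p = 0.0554 with an estimated correlation, with Hoxb4 at 102 against 2 counts. Other PRC2 targets gave 13 rose and 0 fell of 28 with 15 and 0 over the list alone, adjusted p = 6.22e-06, adjusted p = 0.0630 with an estimated correlation, with Pax9 at least 20.7-fold higher and Nkx6-1 4.71 (SE 0.885) up. Trophoblast genes gave 8 rose and 0 fell of 12, adjusted p = 1.55e-04, adjusted p = 0.0785 with an estimated correlation, with Krt18 2.77 (SE 0.476) and Bmp8b 2.79 (SE 0.527) up. The 2-cell-like genes gave 9 rose and 0 fell of 9, adjusted p = 3.28e-08, adjusted p = 0.107 with an estimated correlation, with Zfp352 5.74 (SE 0.94) and Tcstv3 5.91 (SE 0.785) up. PRC2 subunits gave 0 rose and 6 fell of 13 with 1 and 6 over the list alone, adjusted p = 1.64e-07, adjusted p = 0.00663 with an estimated correlation, the deleted Ezh2 being among them. The 12 without it gave 0 rose and 5 fell with 1 and 5 over the list alone, with no directed call (adjusted p = 0.0955), and Eed -0.75 (SE 0.158) was among the falls. Stress genes gave 0 rose and 5 fell of 11, adjusted p = 0.0358, adjusted p = 0.154 with an estimated correlation, with Trib3 -1.82 (SE 0.413) down. The remaining lists under 2i had no directed call. Naive genes gave 1 rose and 1 fell of 14 with 0 and 1 over the list alone, adjusted p = 0.927. General genes gave 0 rose and 3 fell of 10 with 1 and 5 over the list alone, adjusted p = 0.224. Formative genes gave 2 rose and 0 fell of 10, adjusted p = 0.242, and PRC1 subunits 5 rose and 4 fell of 16, adjusted p = 0.927. Streak genes gave 2 rose and 0 fell of 10, adjusted p = 0.224, and neuroectoderm genes 5 rose and 0 fell of 8, adjusted p = 0.0924. Germline genes gave 5 rose and 1 fell of 14 with 5 and 2 over the list alone, adjusted p = 0.638. ERK genes gave 2 rose and 1 fell of 14, adjusted p = 0.989, and Wnt genes 2 rose and 0 fell of 10, adjusted p = 0.512. DNA methylation enzymes gave 2 rose and 3 fell of 8, adjusted p = 0.455. Fibroblast genes gave 1 rose and 0 fell of 15 with 0 and 0 over the list alone, adjusted p = 0.329. Imprinted genes gave 8 rose and 5 fell of 18, adjusted p = 0.853. Outside the lists the epithelial gene Dmkn 6.27 (SE 0.399) rose and the growth factor Fgf17 -6.47 (SE 0.578) fell.

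The effect of medium was read in each genotype. In wild-type cells, TG2A_S2iL against TG2A_ESC (n = 2 each), ERK response genes fell as a group: 0 rose, 10 fell and 4 were not called of 14 (0 and 11 adjusted over the list alone, adjusted p = 7.48e-10, adjusted p = 0.0256 with an estimated correlation). The immediate-early gene Egr1 -5.75 (SE 0.836) and the feedback inhibitors Spry4 -3.95 (SE 0.50) and Dusp6 -2.73 (SE 0.538) fell. General pluripotency genes gave 0 rose and 6 fell of 10, adjusted p = 3.72e-08, adjusted p = 0.0193 with an estimated correlation, with Utf1 -2.54 (SE 0.139) down. Formative genes gave 0 rose and 5 fell of 10 with 0 and 6 over the list alone, adjusted p = 7.44e-08, adjusted p = 0.0193 with an estimated correlation, with Dnmt3a -2.56 (SE 0.178) and Pou3f1 -2.64 (SE 0.544) down. The Wnt target Axin2 1.70 (SE 0.293) and the imprinted gene Plagl1 6.86 (SE 0.632) rose. Gata6 fell by 2.33 (SE 0.744, adjusted p = 0.0315), a call lost without TG2A_ESC replicate 2 (-1.09), TG2A_S2iL replicate 1 (-2.53) or TG2A_S2iL replicate 2 (-2.17), and Sox7 fell by 4.18 (SE 0.786, adjusted p = 0.00129). Ezh2 (0.15 (SE 0.156, adjusted p = 0.541)) and Nanog (0.59 (SE 0.235, adjusted p = 0.0833)) were not called, though Nanog passed by DESeq2, with no filter on low counts and with only the compared groups. In all 4086 genes changed (2055 up and 2031 down), with 2509 without TG2A_ESC replicate 2, 2112 without TG2A_S2iL replicate 1 and 2076 without TG2A_S2iL replicate 2.

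In knockout cells, KO10_S2iL against KO10_SL (n = 2 and 3), called PrE genes were mostly lower under 2i. PrE transcription factors gave 0 rose and 6 fell of 10 with 0 and 7 over the list alone, adjusted p = 0.0356, adjusted p = 0.685 with an estimated correlation. PrE surface genes gave 1 rose and 12 fell of 17, adjusted p = 2.47e-06, adjusted p = 0.162 with an estimated correlation. Genes that fell include Sox17 -3.06 (SE 0.514), Sox7 -3.85 (SE 0.498), Pdgfra -2.40 (SE 0.402) and Cubn -6.05 (SE 1.37), and Gata6 was not called (-1.20 (SE 0.502, adjusted p = 0.0718)) but passed with no filter on low counts and with only the compared groups. ERK genes gave 1 rose and 7 fell of 14, adjusted p = 3.14e-04, adjusted p = 0.263 with an estimated correlation, with Spry4 -3.69 (SE 0.479) down. General genes gave 0 rose and 7 fell of 10, adjusted p = 1.05e-04, adjusted p = 0.162 with an estimated correlation, with Lin28a -2.25 (SE 0.529) down. Formative genes gave 0 rose and 6 fell of 10 with 0 and 7 over the list alone, adjusted p = 0.00464, adjusted p = 0.263 with an estimated correlation, with Dnmt3a -1.85 (SE 0.165) down. The 6482 called genes (3447 up and 3035 down) were 4007 without KO10_S2iL replicate 1, 3847 without KO10_S2iL replicate 2 and 10037 with only the compared groups. The median of all genes in this comparison moved from 0.063 to 0.103 under RLE scaling.

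Whether the knockout effect differed between media was tested as a difference of differences, with TG2A_ESC as the SL control. It called 343 genes (147 positive and 196 negative), with 2922 at an unadjusted p under 0.05, 976 by DESeq2 and 4557 with E14_ESC as control. The side with more genes depended on the settings: 186 were positive and 140 negative under RLE scaling, and 532 and 444 by DESeq2. No landmark gene was called, for example Gata6 (1.14 (SE 0.904, adjusted p = 0.578)) and Pdgfra (-1.0 (SE 0.695, adjusted p = 0.515)). With E14_ESC as control Pdgfra (-3.04, SE 0.742, adjusted p = 0.00639), Pou5f1 (-0.955, SE 0.25, adjusted p = 0.00979), Zfp42 (-0.673, SE 0.162, adjusted p = 0.00593) and Sox2 (0.581, SE 0.189, adjusted p = 0.0316) were called. The other landmark genes were not called there. PrE surface genes had a directed call toward a lower effect under 2i (0 rose and 2 fell of 17 with 0 and 6 over the list alone, adjusted p = 2.41e-05, adjusted p = 0.503 with an estimated correlation), with Sparc -1.23 (SE 0.16) and Serpinh1 -1.65 (SE 0.30) the called members. Hox genes also had a call toward a lower effect (0 rose and 1 fell of 33, adjusted p = 0.0233, adjusted p = 0.584 with an estimated correlation). Formative genes (0 rose and 0 fell of 10 with 2 and 0 over the list alone, adjusted p = 0.0330, adjusted p = 0.584 with an estimated correlation) and ERK genes (0 rose and 0 fell of 14 with 3 and 0 over the list alone, adjusted p = 0.0409, adjusted p = 0.631 with an estimated correlation) had a call toward a higher one. Fgf17 -5.12 (SE 0.696) and Plagl1 -3.44 (SE 0.774), named after their values were seen, differed as single genes. The count was 151 without KO10_SL replicate 2, 146 without KO10_SL replicate 3, 70 without KO10_S2iL replicate 1, 44 without KO10_S2iL replicate 2, 50 without TG2A_S2iL replicate 1 and 58 without TG2A_S2iL replicate 2. With only the compared groups it was 1795, and with no filter on low counts 923.

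Knockout calls were then set beside the PrE calls. The Fisher tests and the interval below treat genes as independent, which they are not, so they understate the uncertainty. Genes up in KO10_SL overlapped those up in C57_PrESC (1658 shared against 1236.1 if independent, Fisher exact odds ratio 1.82, 95% interval 1.69 to 1.96), with 1108 in the opposite direction, and 1662 fell in both (odds ratio 1.59, 1035 opposite). With TG2A_ESC as wild type, chosen after seeing the data, the odds ratios were 2.51 up and 2.34 down. For KO10_S2iL the odds ratios with C57_PrESC were 1.57 up (971 shared, 775 opposite) and 2.80 down (1365 shared, 430 opposite). For KO10_SL with iPrE1 they were 1.29 up (1438 shared, 1487 opposite) and 0.998 down (1285 shared, 1402 opposite, Fisher exact p = 0.969). For KO10_SL with iPrE2 they were 1.22 up (1448 shared, 1525 opposite) and 0.965 down (1307 shared, 1475 opposite, Fisher exact p = 0.359). KO10_SL and KO10_S2iL calls overlapped each other (4.71 up with 1508 shared and 438 opposite, 3.85 down with 1178 shared and 156 opposite). Fold changes of KO10_SL correlated across genes, which are not independent, at 0.58 with KO10_S2iL, 0.096 with C57_PrESC and 0.12 with iPrE1. Genes such as Gata6, Sox17 and Col4a2 rose in both settings, while Nanog fell in the PrE stem cells (-9.09 (SE 0.38) in C57) and was not called in KO10_SL.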

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

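Both differences here come from interaction contrasts planned before the data were examined, and no explanation of them was tested. No group held 4 or more libraries, so no single library was tested against the rest of its group.

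A difference between groups drew attention in 2 places, each by a direct test of the difference. The change from ESC to PrE stem cell differed between the E14 sets and the C57 pair in 6167 genes. Among the landmark genes the E14 change was more positive for Pdgfra (2.03) and for Sox2 (6.65), and more negative for Zfp42 (-3.64). Sox2 stood at 5.31 CPM in iPrE1 and at 2 counts in C57_PrESC, while Zfp42 fell in iPrE1 and was not called in the C57 pair. Zfp42 stood at 50.9 to 59.8 CPM in all PrE stem cell libraries, at 83.7 and 57.6 CPM in C57_ESC and at 765 and 832 CPM in TG2A_ESC. With TG2A_ESC as the SL control, the knockout change differed between 2i and SL in 343 genes, with no landmark gene among them. With E14_ESC as control it differed in 4557 genes, with Pdgfra, Pou5f1, Zfp42 and Sox2 among them.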

How the results depend on the processing

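The fits without the 4 fibroblast-rich libraries, the overlap with TG2A_ESC as wild type and the PRC2 list without Ezh2 were chosen after seeing the data, and all other alternatives were planned. A gene or list with neither value past the threshold counted as the same whatever its sign, and in leave-one-out fits a lone library was assumed to vary like the other groups. Of named gene results, 2866 kept direction and side of the threshold with a library left out, 465 lost the call, 4 gained it and 3 reversed. The counts kept, lost and gained were 725, 9 and 7 by DESeq2, 737, 2 and 2 under RLE, 723, 3 and 15 with no filter, 680, 13 and 17 with only the compared groups, and 717, 23 and 1 with the replicate block. Reversals, all in C57_PrESC against C57_ESC, were Klf4 (1.38) without C57_ESC replicate 1, and Postn (-0.10) and Lum (-1.67) without C57_PrESC replicate 2. At the other end of their ranges, without C57_ESC replicate 2, they stood at -1.02, 9.58 and 9.83. The estimated correlation left 22 list calls of 70. Without Ezh2 in the PRC2 list there were 65: the 4 directed calls of that list were lost, and 1 of PrE transcription factors under 2i (adjusted p from 0.045 to 0.0514). The replicate number was used as a block only as an alternative. Its shared signal was r from -0.013 to 0.115 in KO10_SL and E14_ESC, 0.304 in the C57 pair, 0.458 in iPrE2 and C57_PrESC and -0.529 in iPrE2 and iPrE1.

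With only the compared groups in the fit there were 5383 genes for the C57 pair, 28 for iPrE2 against iPrE1, 3041 for the E14 and C57 difference, 551 for rescued against E14_ESC, 9607 for KO10_S2iL against TG2A_S2iL, 10037 for KO10_S2iL against KO10_SL and 1795 for the difference between media. With no filter the counts were 1143 for iPrE2 against iPrE1, 389 for rescued against E14_ESC and 923 for the difference between media. DESeq2 gave 177 and 976 for the last 2, and the block 6 and 165, with a median recovery on rescue of 0.974. The other wild-type set gave 4863 for KO10_SL, 3798 for the rescued cells and 4557 for the difference between media. With a log2 change of at least 1, recovery on rescue was 0.978. The knockout calls of serum/LIF called back on rescue were then 2834, and the knockout calls of serum/2i/LIF called back on rescue 1270. The cause was not tested for any of these. Whether more genes rose or fell turned under at least 1 alternative for several comparisons. These were iPrE2 against iPrE1, KO10_SL, rescued against KO10_SL and against E14_ESC, KO10_S2iL, both medium changes, the difference between media, and E14_ESC against TG2A_ESC. The 9 results rerun without the 4 fibroblast-rich libraries were gene counts and overlap odds ratios. The counts stayed within 1.5 times those of the main fit, and the odds ratios kept their side of 1 and of the threshold. These fits left 1 library in each of C57_ESC, C57_PrESC, iPrE1 and iPrE2, so they show little about the part played by fibroblast RNA.

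With 1 library left out the counts ran from 9249 to 9612 for iPrE1, 9507 to 9923 for iPrE2, 9727 to 10245 for the C57 pair, 379 to 407 for iPrE2 against iPrE1, 5083 to 6287 for the E14 and C57 difference, 7248 to 7676 for KO10_SL, 5394 to 7173 for rescued against KO10_SL, and 1 to 20 for rescued against E14_ESC. They ran from 2847 to 3156 for KO10_S2iL, 2076 to 3544 and 3847 to 5572 for the medium change in wild type and knockout, 44 to 386 for the difference between media, and 1676 to 4088 for E14_ESC against TG2A_ESC. Odds ratios with C57_PrESC ran from 1.73 to 2.01 and 1.54 to 1.95 in SL and from 1.41 to 1.96 and 2.45 to 3.52 under 2i, up and down, and those with iPrE1 and iPrE2 were not rerun this way. Recovery ran from 0.972 to 1, with 5041 to 6519 genes back in SL and 1533 to 2530 of those selected under 2i.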

Other observations

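Xist and the Y-linked gene Ddx3y differed between groups. Xist, the RNA that coats an inactive X chromosome, stood at 190 and 186 CPM in C57_PrESC, 76.6 and 69.8 in iPrE1 and 25.8 and 24.9 in iPrE2, and at 14.5 CPM or less in every ESC library. The Y-linked helicase gene Ddx3y was at 158 and 150 CPM in C57_PrESC, 0.053 and 2.98 in C57_ESC, 116 and 108 in iPrE1, 33.1 and 39.7 in iPrE2, and 30.8 to 76.2 in the E14-derived ESC libraries. These genes were chosen after their values were seen.

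All tests below were chosen only after the result was seen, except the test for 2 active X chromosomes and the count of library splits. Also set after the values were seen were a requirement that a percentage or ratio pass its bound with any 1 list gene left out, and the division of the test of expression by the PrE stem cells into C57_PrESC and EPZ iPrE. Without that requirement the fibroblast profile test (46.7%, bound under 50%) would have counted against fibroblasts, and the ratio of 5.01 (bound 5) against expression by the EPZ iPrE cells.

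The rise of PrE genes in KO10_SL could come from loss of Ezh2, from the choice of wild type, or from a small admixture or subset of cells with a PrE profile. All 22 of the PrE list members that rose were called lower in the rescued cells (100%). Of the 22, 21 (95.5%) also rose against TG2A_ESC, which speaks against the wild-type choice as the only source. The size of the rise did depend on that choice: the median of PrE transcription factors was 4.556 against E14_ESC and 2.669 against TG2A_ESC. The 22 were selected on the KO10_SL libraries that stand in both tests, which favours both outcomes. If a fixed share of PrE-like cells made the signal, the gain of each PrE-specific gene would be the same share of its gain in iPrE: of 42 such genes, 61.9% lay within 2-fold of the median share of 6.87%, between the bounds of 60% and 80% (61.0 to 63.4% with 1 gene left out). Measured against C57_PrESC the figure was 81.0%, and between the PrE sets themselves 78.6 and 90.5%, so an admixture, or a PrE-like subset that arises with loss of Ezh2, stays open beside a rise in all cells. The splits of the 6 libraries are too few for a share under 0.05: 1 of 10 gave as many calls, the real split 10315 and the highest other 0.

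Fibroblast genes in 4 of the PrE stem cell and C57 libraries may come from fibroblasts or their RNA, or from the PrE stem cells. Of 15 list genes, 7 (46.7%) kept their share of the list sum within 2-fold in all 4 libraries (42.9 to 50% with 1 gene left out), which leaves fibroblasts open. In C57_PrESC 1 replicate held 68.8 times the sum of the other, which speaks against steady expression by those cells. In EPZ iPrE the smaller ratio was 5.01 (4.61 to 5.50 with 1 gene left out), so expression by those cells stays open. Col1a1 reached 709, 146, 88.2 and 56.1 CPM in the 4 libraries.

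The near absence of RNA from 4 Y-linked genes in C57_ESC may mean that most cells there carry no Y chromosome. The highest of the 4, Ddx3y, was at 0.986% of its C57_PrESC level, as that explanation predicts, but Gm47283, also annotated on the Y, stood at 225 and 215 CPM in C57_ESC and 183 and 186 in C57_PrESC. Low Ddx3y as an ESC state is less likely, since the lowest wild-type E14 library held it at 25.6% of that level. Such a state stays open for Kdm5d and Usp9y, at 0.998% of their C57_PrESC level in the highest library of TG2A_ESC and E14_ESC. In iPrE1 Kdm5d stood at 54.7 and 66.3 CPM and Usp9y at 15.4 and 17.6 CPM. In iPrE2 Kdm5d was lower, at 8.10 and 8.95 CPM. Usp9y stood there at 1.51 and 1.38 CPM, against 1.61 and 1.86 CPM in the ESCs of KO10_S2iL. With 2 active X chromosomes, X-linked genes would be higher than autosomal ones in C57_ESC against E14_ESC, and the median log2 difference was 0.088, which speaks against it. Whether Gm47283 reads come from the Y, and whether C57_ESC and C57_PrESC come from the same embryo line, is untested.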
